A study of Mus musculus with 3 samples.

How the data were processed

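Poly(A) site sequencing (PAS-seq, made here with the QuantSeq protocol per the labels) reads the 3′ ends of polyadenylated RNA, so that each read marks a cleavage and polyadenylation site. It was applied to F121-9, a mouse embryonic stem (ES) cell line from a cross of the CAST and 129 strains. The series holds 1 group of 3 libraries, named in the labels as biological replicates 1, 2 and 3, each at passage 14 and made from 500 ng of RNA. The labels name no separate cultures, so the spread between libraries may be partly technical. With 1 group there was no contrast between conditions, and all comparisons were made within the line.

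Each library came as a list of the same 178115 sites. The deposited value of a site is in RPM (reads scaled to the total of the library), as read from the values, since the files have no header line. The deposited lists also give the fraction of the 3 libraries with a read at the site, the mean RPM over the libraries, a region code and the poly(A) signal hexamers near the site. The mean and the fraction were recomputed and matched at 178115 sites. Sites were made from alignments to mm10 with the GENCODE M21 annotation, per the text files deposited with each library. The aligner, the site caller and their versions are not given in the sources used here. How reads that map to several places were treated is not given either, so genes with near-identical copies or pseudogenes are uncertain.

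Whole reads could be recovered from the RPM values: 100% of values were whole multiples of 1 step within 0.01 reads. The steps gave 11085428, 14855484 and 14064461 reads in the RPM denominator of replicates 1, 2 and 3, of which 91.5%, 91.0% and 92.7% lay at listed sites. No molecular identifiers are given in the sources used here, so reads may not be independent molecules, and any counting error given covers counting only. Replicate 3 had no reads on the X, Y, mitochondrial and unplaced contigs. Therefore, as a departure chosen after seeing the data, comparisons over 3 libraries used the 19 autosomes, and genes on X or the mitochondrial genome were given for replicates 1 and 2. At autosomal sites with at least 100 reads in both libraries, the RPM of replicate 3 lay 0.13 (log2) above that of replicate 1 and 0.13 above that of replicate 2, against -0.01 and -0.01 after scaling to autosomal reads.

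Sites were assigned on their strand to GENCODE M21 genes by overlap with a terminal exon, another exon, an intron or the 1000 bases downstream, in this order, and protein-coding genes came first. Where several genes remained, the closest annotated transcript end decided, and 71 tied sites were left out of gene values. The region codes are not explained in the deposited files and were not used. Of 58285 sites with the code TE, 53386 lay in a terminal exon here and 4828 in another exon. Gene levels were RPM summed over exonic and downstream sites. Signals were searched as 18 hexamers in the 40 bases upstream of the site and in a control window of 40 bases from base 100 downstream, in GRCm38. All 145636 deposited hexamers compared with this sequence were found at their place. A site was called A-rich, as possible internal priming, when the 20 bases downstream held at least 12 A or a run of 6 A.

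For tandem sites, the most proximal and the most distal site of the terminal exon with at least 5% of the gene's reads were compared in genes with at least 50 reads. Because the deposited unit is RPM, the test was limma on log2 ratios of RPM with a pseudocount of 0.05 RPM and the library as a block, as the planned design foresaw for files without counts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold ratio. A ratio on the log2(RPM + 0.05) scale understates differences of rarely used sites. For files with counts the planned design named the edgeR quasi-likelihood test, which was run here on recovered reads as an added alternative. On data simulated for this comparison over 5041 genes, with a variance 15 times the mean, 49 of 100 genes with a 4-fold ratio and 78 of 100 with a 16-fold ratio were called, and 8 of 4841 genes with equal sites. Site shares were compared between libraries with a chi-square test per gene (sites with at least 5% of reads, genes with at least 50 reads in every library). On reads simulated with counting error only, this test called 0 of 5007 genes with constant shares. It called 96 of 97 genes whose most used site was raised 3-fold in 1 library. The real libraries spread by more than counting error, so these rates do not carry over to them. AATAAA at proximal and distal sites was compared with an exact McNemar test. Marker lists were compared within each library on medians of log2(RPM + 0.1), with an exact sign-flip test over 3 libraries.

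The tests of the comparisons, the first set of alternatives, the 16 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 genes with the highest mean, up to 4 members of each list with the highest mean, the 10 most-read genes that favoured the proximal and the 10 that favoured the distal site with the same direction in every library, every tandem 3′ UTR example with enough reads, and the 5 genes with the largest variation beyond counting error at a mean of at least 100 reads. List names absent from GENCODE M21 were dropped, and some genes that the rule takes are not reported here. Alternatives covered detection limits, scaling factors, pseudocounts, site and gene minimums, other tests, signal windows, A-rich sites and each library left out. Alternatives added after seeing the data were the edgeR test, pseudocounts of 0.5 RPM for site ratios and 1 RPM for list medians, X-linked genes, sites at least 100 bases apart, the 1000 bases downstream, removal of sites in 1 library only, all contigs, scaling to autosomal reads, intronic sites, removal of the largest site, division of the chi-square by its overdispersion, libraries left out of the correlations, regions and signals, and removal of A-rich sites from the McNemar test. The share of other hexamers among sites without AATAAA and ATTAAA was also computed after seeing the data. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.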

Results

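Poly(A) sites were measured in 3 libraries of F121-9 mouse ES cells, a hybrid line whose 2 parental genomes are CAST and 129. Reads at listed sites numbered 10147672 in replicate 1, 13513327 in replicate 2 and 13040620 in replicate 3. Coordinates below are mm10.

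The first question was which sites the cells used and how well the libraries agreed. Most reads fell on a shared set of sites, while most listed sites were seen in a single library. Of 171741 autosomal sites, 31987 (18.6%) had reads in every library, 24612 (14.3%) in 2 libraries and 115142 (67.0%) in 1 library only. The shared sites held 96.6%, 96.5% and 96.7% of the autosomal reads of replicates 1, 2 and 3. A library had reads at 86776 ± 11776 autosomal sites (mean ± SD, n = 3). Across genes, the Pearson correlation of log2(RPM + 1) was 0.963, 0.948 and 0.959 for replicates 1 and 2, 1 and 3, and 2 and 3. Across sites it was 0.894, 0.862 and 0.887, with Spearman coefficients of 0.175, 0.141 and 0.157, which rose to 0.699, 0.618 and 0.649 at sites with a mean of 10 reads or more. Genes and sites are not independent replicates. No pair of libraries was a copy of another, since the chi-square of gene counts exceeded its degrees of freedom by 20.3, 26.1 and 28.8 times.

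Replicate 3 had 0 reads on the X, Y, mitochondrial and unplaced contigs, and reads on all 19 autosomes. The mitochondrial genome held 4.61% and 3.98% of listed reads in replicates 1 and 2, and the X chromosome 3.28% and 3.36%. In those 2 libraries, 442 X-linked genes with a mean of at least 1 RPM had a median of 15.02 and 15.65 RPM, or 0.991 and 0.983 of the median of 12416 autosomal genes.

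**Figure D1:**
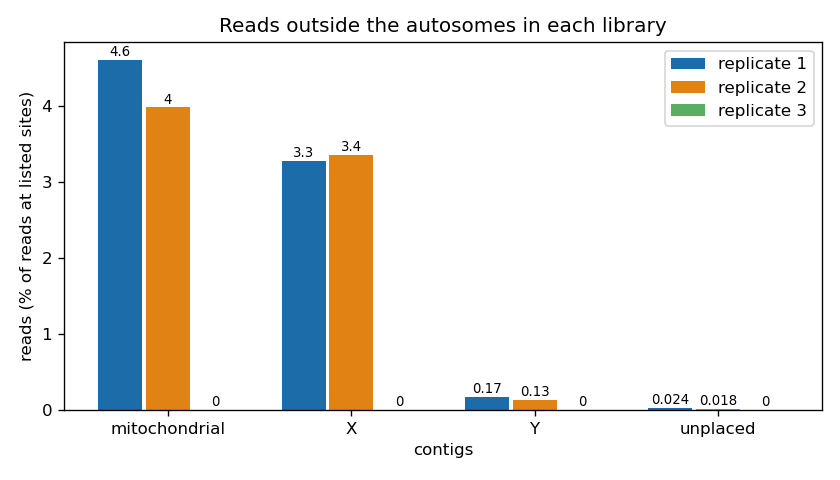
Share of reads at listed sites (y axis, percent) on the mitochondrial, X, Y and unplaced contigs (x axis) in each of the 3 libraries (bars). Replicates 1 and 2 have 3.28% and 3.36% on X, and replicate 3 has 0 on all 4 kinds of contig.

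The next question was where in genes these sites lay and which signals preceded them. Terminal exons, which carry most 3′ UTRs, held 92.8% ± 0.287 of autosomal reads (SD, n = 3) but 30.1% of sites. Introns held 1.51% ± 0.0753 of reads and 21.8% of sites, and sites outside genes on their strand held 2.47% ± 0.127 of reads and 36.7% of sites. Other exons held 2.13% ± 0.141 of reads and the 1000 bases downstream of genes 1.05% ± 0.0426. Of terminal exon sites, 42.6% had reads in every library, against 5.71% of intronic sites. AATAAA, the canonical signal bound by the cleavage machinery, lay upstream of sites with 61.8% ± 0.799 of reads and of 29.7% ± 0.774 of sites, against 2.18% ± 0.0743 of reads and 3.32% ± 0.0957 of sites in the control window. ATTAAA without AATAAA preceded sites with 13.4% ± 0.159 of reads, against 1.33% ± 0.0357 in the control window. Another hexamer without AATAAA and ATTAAA preceded sites with 11.2% ± 0.139 of reads, against 12.9% ± 0.239 in the control window. Of sites it preceded 19.4% ± 0.389, against 17.4% ± 0.182. Of reads at sites with neither AATAAA nor ATTAAA upstream, 45.2% ± 1.73 had another of the 18 hexamers there. Of reads at sites whose control window lacked both, 13.4% ± 0.25 had another in that window. The shares of sites were 31.45% ± 1.09 and 18.4% ± 0.206. Upstream shares of this kind were higher in 3 of 3 libraries, but the compared sets of sites differ. None of the 18 hexamers preceded sites with 13.6% ± 0.926 of reads, and 7.12% ± 0.305 without the largest site. AATAAA preceded 42.5% of sites seen in every library and 19.3% of those seen in 1 only. A-rich sequence followed 11.9% of sites, with 1.76% ± 0.124 of reads.

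Gene levels were asked for the identity of the cells. Genes of core and naive pluripotency were read at high levels, and markers of the germ layers, of trophoblast and of 2-cell-like cells mostly at low levels or not at all. In the core list, 13 of 14 genes reached 1 RPM and 9 reached 100 RPM. They were led by Trim28, a co-repressor that silences retroelements (1476 ± 3.18 RPM, SD, n = 3), Sox2 (611 ± 89.3), L1td1 (493 ± 31.3) and Sall4 (397 ± 30.3). SDs of gene levels are of the deposited RPM, in which replicate 3 lay 0.13 (log2) above the others at well-read autosomal sites. An SD as small as that of Trim28 depends on this scale. In the naive list, all 16 genes reached 10 RPM, led by Tdh, which encodes threonine dehydrogenase (909 ± 84.8), Nanog (723 ± 133), Tfcp2l1 (631 ± 56.6) and Klf2 (586 ± 81.8). Genes of formative and primed pluripotency were lower. Zic2 had 44.0 ± 6.97 RPM, the de novo DNA methyltransferases Dnmt3a and Dnmt3b had 33.5 ± 3.41 and 28.1 ± 4.06, Lin28b had 22.0 ± 6.32, and 1 of 12 genes had no listed site. The median of the naive list exceeded that of this list by 4.05 ± 0.29 (log2, n = 3), higher in 3 of 3 libraries. With 3 libraries the exact two-sided sign-flip p was 0.25, the smallest it can be, and it was 0.25 after Benjamini-Hochberg adjustment over the 14 differences computed.

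Of the 12 genes of the 2-cell-like list, 11 had no listed site and Usp17lc had 0.127 ± 0.111 RPM (0.191 without replicate 3). The list holds near-identical gene copies, among them Zscan4a to Zscan4f, whose reads may have been lost if reads that map to several places were dropped. That treatment is not given, so these values cannot tell silent genes from genes that could not be read. The naive median lay above the endoderm, mesoderm, neuroectoderm, trophoblast and fibroblast medians by 8.29 ± 0.81, 10.08 ± 1.31, 8.57 ± 2.20, 7.38 ± 0.82 and 8.82 ± 1.17 (log2, n = 3), in 3 of 3 libraries each. The sizes rest in part on the pseudocount of 0.1 RPM, since the lower medians were low. With 1 RPM, chosen after seeing the data, the differences were 6.89, 7.38, 6.89, 6.28 and 7.03, in 3 of 3 libraries each. Lama1, a laminin chain, and Ttr led the endoderm list (36.4 ± 2.09 and 34.5 ± 9.12 RPM), followed by Gata4 (2.34 ± 1.79) and Dab2 (2.32 ± 1.45), which had 1.30 and 1.48 without replicate 3. In mesoderm, Gsc had 11.8 ± 8.76, T 6.93 ± 4.06, Eomes 2.24 ± 0.800 and Twist1 1.28 ± 1.15 RPM, while Gsc had 6.74 without replicate 3 and Twist1 0.812 without replicate 2. In neuroectoderm, the cytoskeletal genes Map2 and Tubb3 had 54.5 ± 34.9 and 34.4 ± 10.1 RPM, Hes5 10.7 ± 9.05 and Nes 5.12 ± 1.57, while Map2 had 34.7 and Hes5 5.96 without replicate 3. Tfap2c led the trophoblast list (188 ± 39.7 RPM), above Krt7 (10.3 ± 1.09), Ascl2 (7.73 ± 2.38) and Krt8 (3.74 ± 1.33). Of 19 autosomal genes of these 4 lineage lists at 1 RPM or more, 10 were highest in replicate 3 (9 when scaled to autosomal reads), as were 11 of 15 naive genes (7 when so scaled). Of the fibroblast list, written for feeder cells, Fn1 (fibronectin) had 805 ± 36.2, Thy1 84.4 ± 37.1, Vim 71.6 ± 22.4 and Col6a1 11.8 ± 2.37 RPM. These 4 were the only members at 10 RPM or more. The list median was 0.997 RPM, 7 of 14 genes reached 1 RPM and 3 had no listed site, so the named genes do not stand for the list.

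**Figure D2:**
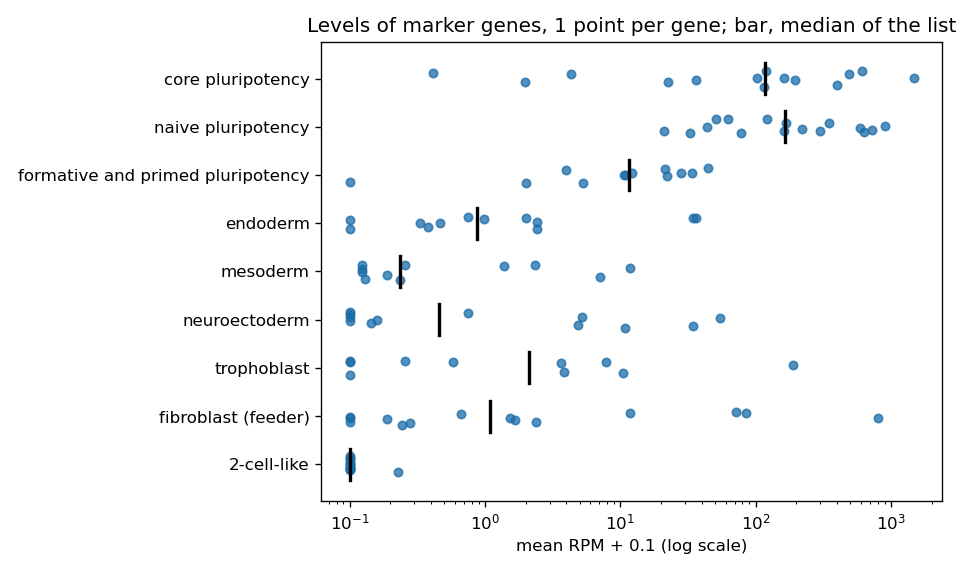
Mean RPM of each gene of 9 marker lists plus 0.1 (x axis, log scale), with 1 point per gene and a bar at the median of the list. Points of the core and naive lists lie mostly above 10 RPM, and 11 of 12 genes of the 2-cell-like list have no listed site.

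Cell cycle genes were all read at 10 RPM or more (16 of 16), led by Top2a (869 ± 69.4 RPM) and the replicative helicase genes Mcm3 (625 ± 23.8), Mcm2 (611 ± 26.1) and Mcm5 (393 ± 39.3). Replication-dependent histones, whose mRNAs mostly lack poly(A) tails, were low: 1 of 20 genes found in the annotation reached 10 RPM, Hist1h1c (10.7 ± 3.86), followed by Hist1h3c (9.49 ± 1.91) and Hist1h2ag (4.44 ± 2.35). These counts leave out H1f0 (22.5 ± 1.54), which the planned lists placed under both kinds of histone and which encodes a replication-independent linker histone. Of the replication-independent histones, H2afz (566 ± 10.3), H3f3b (413 ± 13.5), H2afv (354 ± 61.04) and H2afy (123 ± 26.8) were the highest. Of the imprinted genes, Snrpn had 339 ± 21.1, Plagl1 154 ± 24.7, Impact 60.0 ± 4.18 and Igf2r 24.4 ± 9.14 RPM. Genes of X inactivation were given for replicates 1 and 2. The ubiquitin ligase gene Rlim had 35.1 ± 1.72, Tsix 6.25 ± 4.17, Ftx 0.135 ± 0.190 and Jpx 0.0673 ± 0.0952 RPM (SD, n = 2), and 1 of the 5 genes had no listed site. Of 24 genes in the list of cleavage and polyadenylation factors, 23 reached 10 RPM. The highest was Pabpc1 (548 ± 76.6), which the planned list included although it encodes a cytoplasmic poly(A)-binding protein and no cleavage factor. Cpsf1 (253 ± 4.24), the X-linked Cstf2 (246 ± 5.75, n = 2) and Cpsf3 (200 ± 22.6) followed.

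The highest values of all belonged to 1 site at position 39847545 of chromosome 17, in the terminal exon of Gm42418, which took 6.03% ± 0.551 of the reads in the RPM denominator (SD, n = 3). Gm42418 overlaps a ribosomal RNA-like sequence, and its level is uncertain. The mitochondrial genes mt-Nd4 (23680 ± 4531 RPM, n = 2) and mt-Cytb (7384 ± 955, n = 2) were also among the highest, as were Rack1 (4446 ± 324) and the ribosomal protein genes Rpl32 (5513 ± 309), Rps20 (5459 ± 856), Rpl13 (5303 ± 873) and Rpl8 (4663 ± 272). Ribosomal protein genes have many processed pseudogenes, so these levels are uncertain. Of 12416 autosomal genes at a mean of 1 RPM or more, 7532 reached 10 RPM and their median coefficient of variation over the libraries was 17.5%. At a mean of at least 100 reads, the 5 genes with the largest variation beyond counting error were Gm6158 (19.98 RPM in replicate 3 against 0.271 and 3.30), Drd1 (18.98 against 3.43 and 0.0673), N6amt1 (18.7 against 1.80 and 2.09), Atxn2l (33.3 in replicate 2 against 3.34 and 5.97) and Trip10 (28.9 in replicate 2 against 5.50 and 4.20). All had a mean under 300 reads. Over the 2857 genes with 100 to 300 reads, the spread between libraries averaged 19.4 times counting error. The ranking took out counting error only, so it cannot tell these 5 genes from the general spread of genes with few reads.

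The main comparison set the most distal against the most proximal site of the terminal exon, a choice that changes 3′ UTR length. Use leaned to the distal site, and AATAAA lay more often upstream of the distal site over all tested genes, though not by the test in genes that favoured the proximal site. Of 5041 genes tested, 1479 (29.3%) used the distal site more and 612 (12.1%) the proximal site more, by limma with Benjamini-Hochberg adjustment at 2-fold or more. Of the 2091 calls, 2088 had the same direction in every library, which the test nearly requires of a call. Among all 5041 tested genes, called or not, 3546 had the same direction in every library. The median log2 ratio of distal over proximal was 1.33, and the median distance was 845 bases (quartiles 232 and 1896). The distal site had 70.0% ± 0.193 of the reads at both sites in the median gene, and 57.0% ± 0.523 of these reads pooled over genes (SD, n = 3). At site minimums of 10% and 1% in place of 5%, which change the genes tested, the median ratio was 0.75 and 2.83 and the distal calls were 819 and 3142. Without replicate 2 the calls were 777 and 370, and with TMM factors over the 6 columns the median was 0.44 and the calls were 794 distal and 896 proximal, a split set by the centring of the ratio.

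Among the most-read genes that favoured the proximal site, Rpl22 put 6.83% ± 0.973 of its reads at the 2 end sites on the distal one (SD, n = 3; log2 ratio -3.78, SE 0.12, limma adjusted p = 6e-06). Its sites were at 152332490 and 152334067 on chromosome 4. Npc2, a lysosomal cholesterol transport gene, had 7.12% ± 0.476 distal reads, Rplp0 7.59% ± 1.31, Ywhae 9.54% ± 1.83, Rad23b 13.1% ± 2.57, Tubb5 14.1% ± 4.81, Anp32b 14.4% ± 1.17, Eif4ebp1 14.7% ± 1.92, Hnrnpa0 24.5% ± 5.24 and Cct5 29.9% ± 3.14. Tubb5, a beta-tubulin gene at 35833921 to 35838306 on chromosome 17, had sites at 35834807 and 35833926. The most-read genes that favoured the distal site included the translation factor genes Eef2 (93.2% ± 0.794) and Eif3a (86.6% ± 3.28), the small GTPase gene Rhoa (92.7% ± 0.764), the chaperonin genes Cct8 (87.5% ± 2.12) and Cct6a (87.4% ± 0.649), Psat1 (81.4% ± 0.577), Atp5a1 (78.4% ± 4.95), Hnrnpab (76.5% ± 4.78), Set (73.9% ± 2.31) and Ash2l (70.2% ± 5.32). The sites of Eif4ebp1, Cct5, Cct8 and Npc2 lay only 44, 68, 74 and 95 bases apart, so these 4 genes had no test at a distance of at least 100 bases. Between the 2 most used sites, Hnrnpab and Rad23b turned direction, but Rad23b (log2 ratio 0.79, limma adjusted p = 0.0019) lay under the 2-fold limit and was not called. Atp5a1 (log2 ratio -0.27 against 1.89, limma adjusted p = 0.17) and Set (0.24 against 1.504, limma adjusted p = 0.19) were no longer called there either. Hnrnpab and Rad23b also turned at a site minimum of 10%, where Rpl22, Npc2, Rplp0, Eef2, Rhoa and Eif3a had no test, and Cct8 turned at 1%, where the ratios of Cct6a, Set and Eif4ebp1 were 6.24, 5.27 and -4.12 against 2.79, 1.504 and -2.55.

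Of the 20 tandem 3′ UTR examples, 12 had a testable pair of sites, of which 5 were called distal and 3 proximal, the same counts when adjusted over the list alone. Distal use was higher in, among others, Ccnd1 (88.4% ± 5.97 of reads at the end sites), Rac1 (84.02% ± 5.94), Hmga2 (79.9% ± 8.33) and Pak2 (69.8% ± 3.31). Proximal use was higher in Cdk6 (7.82% ± 7.60 distal), in Dicer1, the microRNA-processing nuclease gene (19.04% ± 2.43), and in the RNA helicase gene Ddx5 (27.8% ± 1.71). Timp2 (63.1% ± 8.57), Pafah1b1 (59.2% ± 1.79), Calm3 (49.99% ± 2.19) and Nudt21 (65.8% ± 57.0, with 101 reads, an uncertain level) did not pass the test. Pak2 turned direction between its 2 most used sites (-0.063, limma adjusted p = 0.89) and was not called without any 1 of the libraries or by edgeR on recovered reads, where its log2 ratio stayed at 1.08 to 1.31 and at 1.21, against 1.21. Cdk6 had 0 distal reads in replicate 1, so its log2 ratio of -4.48 rests in part on the pseudocount: it was -2.94 without replicate 1 and -3.22 with 0.5 RPM, and at a site minimum of 1% it was -1.07 and not called. At 1% the ratio of Pak2 was 4.22, at 10% that of Ccnd1 was 1.98 against 3.08, and Cdk6 and Nudt21 had no test at 10%. Among the cleavage and polyadenylation factors, 3 of 9 tested genes favoured the proximal site (Ppp1cb, Pabpn1 and Cstf1) and 3 the distal one (Pcf11, Cpsf2 and Cpsf6). In the naive list, 4 of 6 tested genes favoured the distal site (Klf4, Stat3, Klf5 and Nr5a2) and 0 the proximal one. In the core list 3 of 5 favoured the distal site (Tdgf1, Lin28a and Dppa2) and 1 the proximal one (Gdf3), and in the cell cycle list 3 of 7 the distal (Cdc20, Cdk1 and Plk1) and 2 the proximal one (Pcna and Mcm3). Of 9 imprinted genes tested, 2 favoured the distal site (Impact and Mest), as did 1 of 4 formative and primed genes (Sox4), and 0 the proximal one. Of 5 genes tested in each histone list, H1f0 favoured the proximal site in both, and Hist1h1c and H2afy the distal one. The 2 endoderm genes and the 1 gene each of mesoderm, neuroectoderm and trophoblast with a testable pair did not pass the test. Adjusted over the list alone, the distal counts were 2 in the formative and primed list, 1 in trophoblast and 2 in the replication-independent histones, and the other counts were the same. The genes of these lists, from Ppp1cb on, were named after their values were seen.

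**Figure D3:**
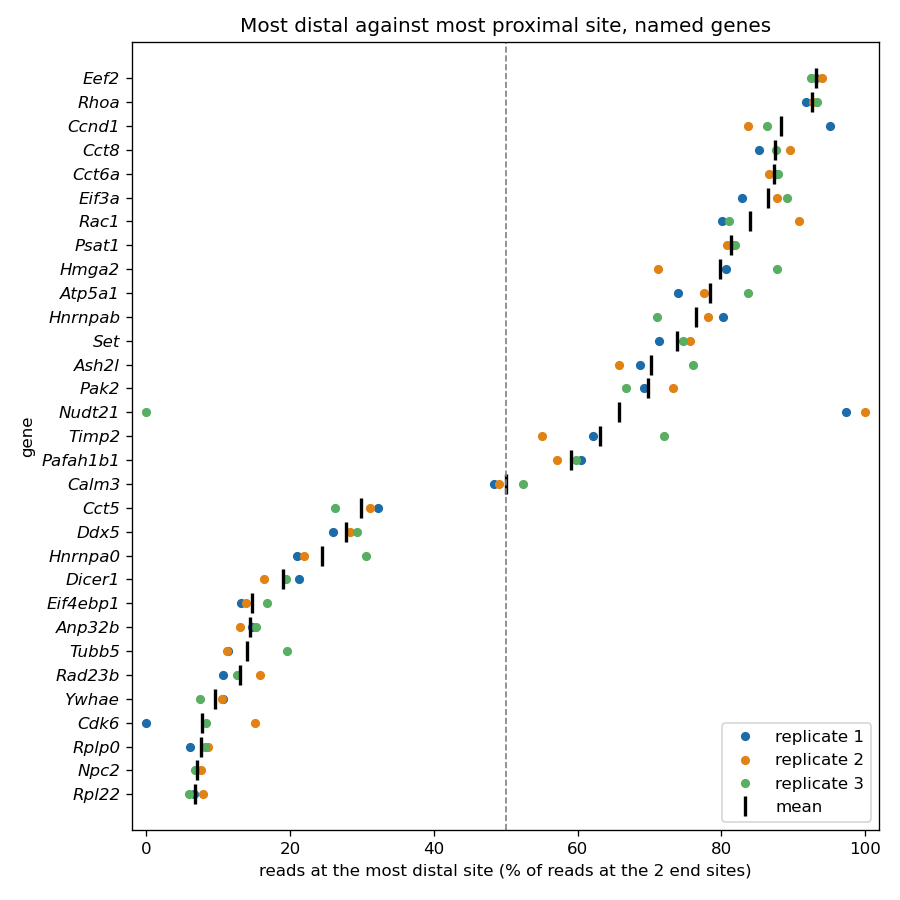
Reads at the most distal site as a percent of reads at the most distal and most proximal sites (x axis) for the named genes (y axis), with 1 point per library and a bar at the mean. Rpl22 and Npc2 lie near 7% and Eef2 and Rhoa near 93%, while the libraries of Nudt21 (101 reads) lie at both ends.

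AATAAA lay upstream of 60.2% of distal and 31.2% of proximal sites. In 2026 genes only the distal site had it and in 565 only the proximal site (exact McNemar p = 7.7e-192), where genes are not independent replicates. In genes that favoured the proximal site, AATAAA lay upstream of 51.3% of proximal and 52.6% of distal sites (exact McNemar p = 0.67). In genes that favoured the distal site it lay upstream of 24.4% and 69.0% (exact McNemar p = 9.8e-129).

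The last comparison asked whether the share of reads per site varied between libraries by more than counting error. It did in nearly all genes: 4143 of 4549 (91.1%) passed an adjusted p of 0.05 in the chi-square test. The median statistic was 18.8 times its expected median, and after division by this factor 14 genes (0.308%) passed. The chi-square treats reads as independent molecules, so its count of genes does not measure differences in site choice.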

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

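The 4 tests on the reads of replicate 3 were chosen after the result was seen. Signal lay outside the comparisons over 3 libraries, above the limit of 3 reads that a count of 0 allows: 467923 and 538488 mitochondrial reads in replicates 1 and 2, 333238 and 453670 X-linked reads, and 17674 and 18035 reads on the Y chromosome. Of the Y reads, 16730 and 17446 lay at 1 site at position 90739257, outside annotated genes.

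Replicate 3 had none of these reads. Removal of mitochondrial and sex-chromosome reads would have left the unplaced contigs, where replicate 3 had 0 reads against 2473 and 2388 in the others. Loss of an X chromosome would have left X-linked reads, of which replicate 3 had 0%. A table made from alignments that stop after chromosome 9 in text-sorted order stays open as a candidate explanation: 0 reads lay on contigs that sort after it, and autosomal reads made up 92.7% of the RPM denominator of replicate 3, against 84.1% in replicates 1 and 2, as if that denominator left out the missing reads. No biological explanation other than the loss of X was tested.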

How the results depend on the processing

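The edgeR test on recovered reads, the use of all contigs, the removal of the largest site, the division of the chi-square, the libraries left out of the correlations, regions and signals, and the other added alternatives named with the processing were chosen after seeing the data. Mean sites per library were 49462 at 5 reads and 31866 at 1 CPM, and 80005 to 90698 with 1 library left out. Sites in every library were 18159 at 1 CPM and 36900 to 41875 with 1 library left out. Correlations across sites were 0.852 at a mean of 10 reads, 0.658 with log2(CPM + 0.1), 0.862 on all contigs and 0.862 to 0.894 with 1 library left out; across genes they were 0.937, 0.893, 0.925 and 0.948 to 0.963. Terminal exons held 93.4% of reads at sites with 10 reads, 94.0% without A-rich sites and 92.3% without the largest site. AATAAA preceded 27.1%, 30.6%, 31.3% and 42.5% of sites with 30 bases, with 50 bases, without A-rich sites and at 10 reads, and 55.6%, 63.5% and 62.7% of reads with the first 3. Genes favouring the distal site were 819 and 3142 at site minimums of 10% and 1%, which change the genes tested (3818 and 7050), 794 with TMM factors, a split set by centring, and 777 to 1337 with 1 library left out; proximal calls were 370 to 568. The edgeR test called 1354 distal and 571 proximal genes and DESeq2 1691 and 714. Log2 ratios turned sign between the 2 most used sites in Atp5a1 (-0.27), Hnrnpab (-1.87), Pak2 (-0.063) and Rad23b (0.79), which compares other sites by construction, and Atp5a1 and Pak2 did not pass the test there. They also turned at a site minimum of 10% in Hnrnpab (-1.87) and Rad23b (0.79), at 1% in Cct8 (-3.48), with TMM factors in Pafah1b1 (-0.39) and Timp2 (-0.14), and in Calm3 (-0.073 to 0.045 with 1 library left out), where no value passed the test. At 0.79, Rad23b was under the 2-fold limit with the 2 most used sites and at 10%, so it was not called there. TMM factors moved 29 of 31 named ratios by -0.93 within 0.05 (log2), through centring, so the 6 named calls lost and the 2 turns with them say nothing of single genes. Genes whose site shares differed were 2441 at 200 reads, which leaves fewer genes tested, 14 after division by the overdispersion and 3464 to 3866 with 1 library left out. Where not stated, the cause was not tested. The naive list stayed above the primed list (3.91 to 4.20 with 1 library left out), and AATAAA stayed more frequent at distal sites over all tested genes in all alternatives run.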

Other observations

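The test of A-rich sequence at sites of a single library, the slopes over parts of the range of reads and the comparison of gene totals with site shares were chosen only after the result was seen. Several genes of the cleavage and polyadenylation machinery had reads at intronic sites. Nudt21 had the highest share of the 23 genes, 17.9% ± 7.03 (SD, n = 3), on 123 reads. Its level of 2.60 RPM was the lowest of the list, and share and rank are too high if exonic reads were lost where reads map to several places, a treatment not given in the sources used here. Papola, the poly(A) polymerase gene, had 11.1% ± 2.20 of its reads there (SD, n = 3), mostly at position 105836255 of chromosome 12, a site with AATAAA upstream that took 8.56% of the gene's reads. Cpsf6 had 6.48% ± 1.28, mostly at position 117351237 of chromosome 10, also with AATAAA. Wdr33 had 5.29% ± 2.81, Cstf3 3.58% ± 3.08 and Pcf11 0%. The hypothesis that the list as a whole had a higher intronic share than lists matched on reads was not borne out, since its median of 0.388% over 23 genes lay at percentile 74.0 of 10000 matched lists. Nudt21, Papola, Cpsf6, Wdr33, Cstf3 and Pcf11 were named after their values were seen.

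The spread between libraries exceeded counting error also within genes, where the chi-square of site shares was 19.7 times its degrees of freedom on average, which differences in gene expression between the cultures would not give. In the 846 genes with 3000 or more reads, the same ratio was 42.8 for gene totals and 27.2 for site shares, 1.57 times as high (95% bootstrap interval 1.39 to 1.81), so differences in expression stay open there as a further source of the spread between gene totals. The log-log slope of the ratio for site shares on a gene's reads was 0.23 over all genes (95% bootstrap interval 0.182 to 0.280). In genes with under 10000 reads it was 0.0990 (0.0633 to 0.132). This argues against differences in site choice between the cultures as the main source of the spread in these genes. Smaller differences cannot be excluded, since a spread of this size from another source would hide them. Over the 846 genes with 3000 or more reads the slope was 0.634 (0.426 to 0.846). There the ratio rose from 22.5 at 3000 to 10000 reads to 47.4 in the 160 genes above. Differences in site choice thus stay open for the most-read genes. The 686 genes with 3000 to 10000 reads are in both of the partial slopes. Several reads copied from 1 molecule stay open as a candidate explanation, which the ratio of 19.7 meets.

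A total of 23104 autosomal sites had 10 or more reads in 1 library and 0 in the others, with a median of 16 reads. Only 11.2% of them lay within 100 bases of a site read in another library, which argues against a shared site placed some bases apart. A-rich sequence followed 12.8% of these sites, against 8.23% of sites read in all 3 libraries. The share was higher here, but its size argues against internal priming as the main source. AATAAA preceded 28.6% of the single-library sites. What made these sites stays open.

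Swapping the proximal and distal site within libraries gave 4 splits, too few for a share under 0.05. Of these, 1 (the real one) gave 2091 genes and the highest other split gave 0. Each other split reversed the ratio in 1 of the 3 libraries, so genes with a consistent ratio lost their call by construction. The 0 therefore does not bear on chance.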
